A study of Mus musculus with 10 samples.

How the data were processed

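The series profiled CD4+ T cells from the mesenteric lymph nodes of female C57Bl/6 mice with Affymetrix MOE430A 2.0 arrays. Per the labels, lymph node cells were freed of erythrocytes, depleted of MHC class II+ cells with microbeads, treated with an Fc block and sorted as CD4+CD25hi cells (Treg) or CD4+CD25- cells (Teff). The mice were naive, called resting here, or had been given 100 Schistosoma mansoni cercariae under the skin and were killed after 9 weeks. The 10 arrays form 4 groups: 2 of Teff and 2 of Treg from resting mice, and 3 of Teff and 3 of Treg from infected mice. The labels name 2 naive and 3 infected mice and independent sorts, so cells of both types may come from the same mice, but they do not pair the arrays. For each sample 200 ng of total RNA was amplified and labelled with biotin.

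The deposited table holds 1 intensity per probe set and array on a linear scale, from 2.64 to 13510.95, with array medians from 34.59 to 39.56. The submitters' processing notes name RMA and the affy package without a version or further settings. The values were turned into log2 values here, a step added once the linear scale was seen, and were not normalised again in the primary comparisons. The table gives no detection calls and no depth, so the number of arrays limits the precision.

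Of 22690 probe sets, 64 were array controls. Of the 22626 others, 20380 carried a single gene symbol, 691 carried several, and 1555 were not listed in the probe set annotation supplied with the data. Symbols were checked against a RefSeq gene table through their gene ID, which changed 0 symbols and did not match the IDs of 29 probe sets, whose symbols were kept. Each gene was represented by the probe set with the highest mean over the 10 arrays, which left 12393 genes, 4956 of them with more than 1 probe set. No filter on level was applied. The 25th percentile of the gene means was 3.53 on the log2 scale, and folds of genes below this level in either group may be too small.

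The comparisons were Treg against Teff in resting mice, Treg against Teff in infected mice, infected against resting Treg, infected against resting Teff, and the interaction, which is the infection response of Treg minus that of Teff. All used limma 3.58.1 in R 4.3.3, with a mean for each of the 4 groups, a spread per gene pooled over all 10 arrays (6 residual and 5.65 prior degrees of freedom), a two-sided moderated test and Benjamini-Hochberg adjustment over all genes, at an adjusted p of 0.05. A gene called higher or lower passed that threshold. Errors beside log2 changes are standard errors from this model, and errors beside group means are standard deviations. Similarity of a pair of comparisons was measured with Pearson's r across genes, without a p-value, because genes are not independent replicates.

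For each comparison the text names the 10 called genes with the largest increase and the 10 with the largest decrease whose arrays did not overlap between the groups. By chance 33.3% of unchanged genes would not overlap with 2 arrays against 2, 20% with 3 against 2 and 10% with 3 against 3. Where fewer than 5 genes were called in a direction, the 5 with the smallest p are given. Up to 4 genes of each list spoken of, chosen by smallest p, and the sort and lineage genes Il2ra, Cd4, Foxp3, Ctla4 and Ikzf2 are also named. Symbols that are only model or clone names and antigen receptor segments are counted but not named. These rules, the comparisons and the gene lists were fixed before the data were examined.

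The 32 gene lists cover T cell states, pathways and 10 other cell types that a sort could hold. T cell state lists share genes, so their results are not independent. Il21 is in the Th2, Th17 and T follicular helper lists, and Il4 is in the Th2 and T follicular helper lists. Gzmb is in the Treg signature, effector Treg, Th1 and granzyme lists. Each was tested with camera in limma at a preset correlation of 0.01 between genes, adjusted over the 32 lists. The same test with a correlation estimated from the data, and fry, which asks whether the genes of a list move on balance 1 way, were run beside it. List counts are given over all genes tested and adjusted over the list alone. Of all tests of 32 lists in 5 comparisons, 58 passed with the preset correlation and 5 with the estimated one. The lists for apoptosis regulators, cholesterol synthesis, interferon response, chemokine receptors and integrins, dendritic cells, myeloid cells, ribosomal proteins, stromal and endothelial cells, and TGF-beta and Smad signalling passed in 0 comparisons.

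Alternatives planned in advance were quantile normalization, an intensity trend with a robust prior, array weights (statmod 1.5.0), genes above the median level only, the mean of all probe sets of a gene, single probe sets, only the groups compared, stricter thresholds, a block for the replicate number, and leaving out each array in turn. When this leaves a lone array in a group, that array is assumed to vary like the other groups. After the data were seen, 3 more were added. These were a covariate for the ratio of the 3' over the 5' probe sets of spiked control transcripts, leaving out a pair of arrays with high neutrophil genes, and a crossed replicate block in resting mice.

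The model was tested on simulated data with the spread of the real arrays and 50 genes changed by each of several folds. It called 50 to 70% of genes changed 2-fold in the 4 group comparisons and 28% in the interaction. At 4-fold it called 94 to 100% and 92%, with 0 in the wrong direction. It also called from 4 unchanged genes, for infection in Teff, to 15, for infection in Treg. A planted list of 30 genes reached an unadjusted p under 0.05 in 5 of 5 comparisons and an unchanged list in 0 of 5. The simulated noise was independent between genes. The estimated correlation within the real lists reached 0.628 for the cell cycle and 0.714 for myeloid genes. The simulation therefore does not show how the list test behaves with correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.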

Results

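Gene expression was measured on 10 arrays of sorted CD4+ T cells from mouse mesenteric lymph nodes. There were 2 arrays of Teff (CD4+CD25-) and 2 of Treg (CD4+CD25hi) from resting mice, and 3 arrays of Teff and 3 of Treg from mice infected with the trematode worm Schistosoma mansoni for 9 weeks. The series asks which genes differ between Treg and Teff in resting and in infected mice. The number of arrays limits the precision, and Treg and Teff arrays may share mice. Log2 levels of arrays in the same group correlated at 0.981 to 0.994. Arrays of different groups correlated at 0.967 to 0.991, so these ranges overlap.

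Il2ra encodes CD25, the protein the cells were sorted on, and so checks the labels. Its mean log2 level was 4.03 ± 0.25 (SD, n = 2) in resting Teff and 9.41 ± 0.13 (SD, n = 2) in resting Treg. In infected mice it was 4.71 ± 0.27 (SD, n = 3) in Teff and 9.59 ± 0.39 (SD, n = 3) in Treg. By its brighter probe set Cd4 passed in no comparison, with log2 differences of -0.38 and -0.18 between Treg and Teff in resting and infected mice (adjusted p = 0.891 and 0.81). Its dimmer probe set (mean 5.82) was lower in infected than in resting Treg (-1.59, adjusted p = 0.0435 among single probe sets).

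**Figure D1:**
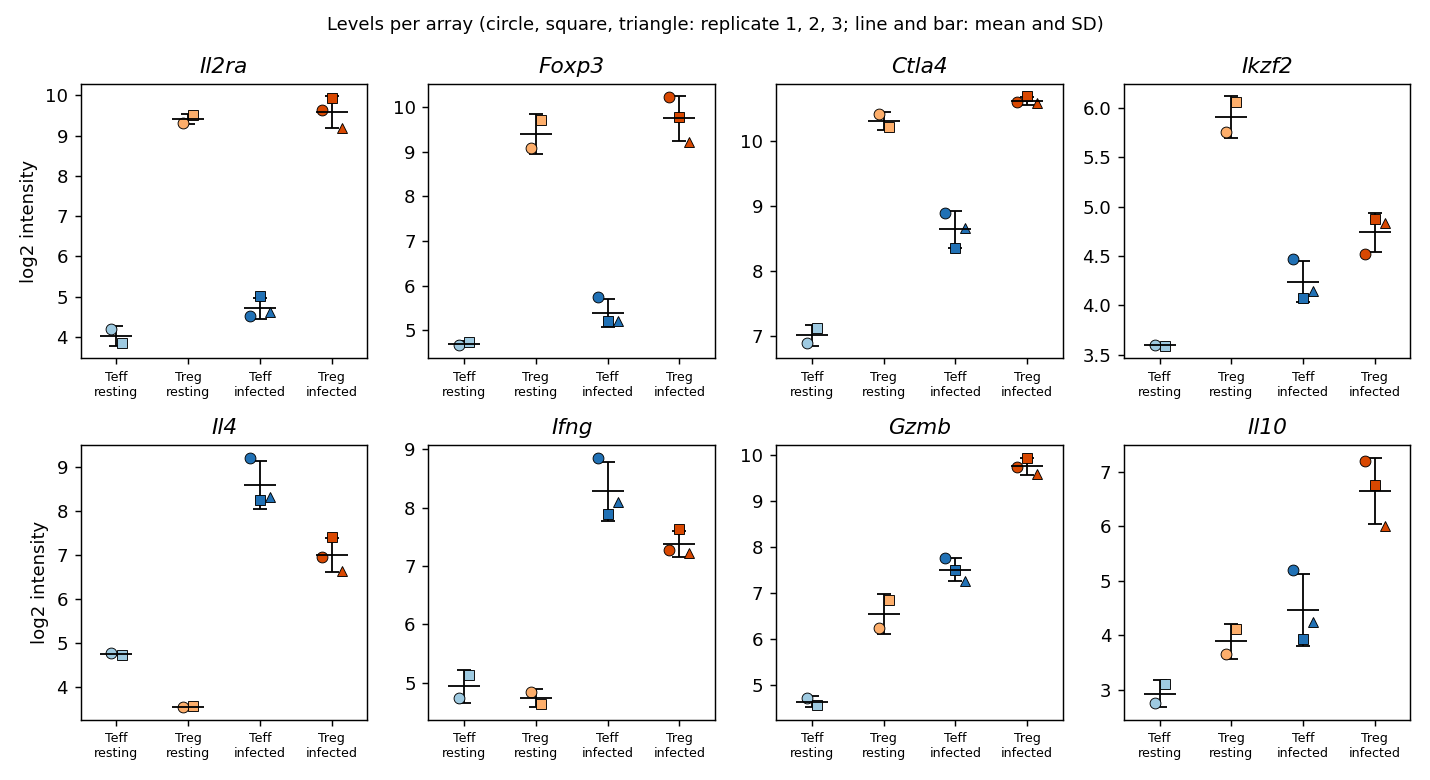
Log2 intensity of 8 genes on each of the 10 arrays, by group. Points are arrays and bars are the mean ± SD of a group. Il2ra averaged 9.41 in resting and 9.59 in infected Treg, against 4.03 and 4.71 in Teff, while Il4 and Ifng were higher in both cell types of infected mice.

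The comparison of Treg with Teff in resting mice asks what sets the regulatory cells apart without infection. Genes of the regulatory lineage were far higher in Treg. Il2ra was 41.5-fold higher (log2 difference 5.38 ± 0.25, adjusted p = 7.37e-07) and Foxp3, the lineage-defining transcription factor, 26.1-fold higher (4.70 ± 0.31, adjusted p = 7.21e-06). Ctla4, an inhibitory receptor, was 9.83-fold higher, and the Ikaros family transcription factors Ikzf4 and Ikzf2 were 9.61-fold and 4.98-fold higher. Other genes with large increases were Penk, which encodes the opioid precursor proenkephalin (14.6-fold), Rgs1, a regulator of G protein signalling (12.8-fold), the orphan receptor gene Gpr83 (12.6-fold), Klrg1, an inhibitory lectin-like receptor (12.4-fold), the zinc finger gene Plagl1 (9.93-fold) and Socs2, a suppressor of cytokine signalling (9.56-fold). The genes most reduced in Treg were Pdlim4 (29.1-fold lower), Nacc2 (10.4-fold), App (8.31-fold), Igfbp4 (7.44-fold) and Klrd1, a receptor of NK and cytotoxic T cells (6.94-fold). Klra17, Ggt5, Tdrp, Adh1 and the kinase gene Sgk1 were 5.64-fold to 6.70-fold lower.

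Of the 24 measured genes of the Treg signature list, 22 were higher in resting Treg and 0 lower (23 higher adjusted over the list alone; camera adjusted p = 2.53e-64, and 0.00216 with an estimated correlation). Of 28 T cell activation and co-receptor genes, 12 were higher, among them the receptor genes Tnfrsf9 (log2 difference 2.74) and Cd83 (2.73). Adjusted over the list alone 17 were higher and 1 lower (adjusted p = 2.59e-24, and 0.0401 with an estimated correlation). Of 21 effector Treg markers, 10 were higher, including Ebi3 (2.62), a subunit of interleukin 35, and Gzmb (1.90), the protease granzyme B. Adjusted over the list alone 14 were higher (adjusted p = 7.37e-21, and 0.0411 with an estimated correlation). Among 31 immediate early and stress genes only Dusp1, a phosphatase (2.04), was called, with 5 higher adjusted over the list alone, and the list as a whole was higher (adjusted p = 0.000189, and 0.0411 with an estimated correlation).

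A further set of lists passed camera with the preset correlation but not with the estimated one. By fry, the naive T cell, NF-kB and Th17 lists passed (adjusted p = 0.00521, 0.00521 and 0.0328). The cell cycle, NK and CD8 T cell lists did not pass fry (adjusted p = 0.461, 0.0853 and 0.0926). Of 15 genes of naive T cells and lymph node homing, 5 were lower in resting Treg, 7 adjusted over the list alone, including Igfbp4 (-2.90), Actn1 (-0.98), the transcription factor gene Lef1 (-1.60) and Satb1 (-1.21; list adjusted p = 1.41e-07, and 0.0697 with an estimated correlation). Of 21 NF-kB pathway genes, 4 were higher (Cd83, Lta, Nfkbiz and Traf1), while adjusted over the list alone 13 were higher and 1 lower (adjusted p = 1.54e-10, and 0.0852 with an estimated correlation). Of 47 cell cycle genes, Tk1 (1.53) and Mcm5 (0.81) were higher, 4 adjusted over the list alone (adjusted p = 5.91e-08, and 0.594 with an estimated correlation). Of 7 Th17 genes, Ccr6 (2.09) and Ahr (1.33) were higher, with 2 higher and 1 lower adjusted over the list alone (adjusted p = 0.0446, and 0.228 with an estimated correlation). Of 15 NK genes, 3 were lower (Prf1, Klrc1 and Klrd1), as adjusted over the list alone (adjusted p = 0.00202, and 0.307 with an estimated correlation). Of 12 CD8 T cell genes, Ccl5, Gzmk and Klrd1 were lower and Cst7 was higher, with 5 lower and 1 higher adjusted over the list alone (adjusted p = 0.0108, and 0.298 with an estimated correlation). The CD8 list missed the threshold without Treg_resting replicate 1 (adjusted p = 0.058), and the Th17 list missed it without each 1 of the 4 resting arrays (adjusted p = 0.107 and 0.0532 without Teff_resting replicate 1 and 2, 0.0915 and 0.053 without Treg_resting replicate 1 and 2). These lists are not specific to other cells: 8 of the 12 CD8 genes and 5 of the 15 NK genes are also in another list.

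In the test over all 12393 genes, 386 differed between Treg and Teff of resting mice, 251 higher and 135 lower in Treg, and 281 of them by at least 2-fold. Leaving out Teff_resting replicate 1 or 2 or Treg_resting replicate 1 or 2 left a lone array in a group, and fewer genes were then called. The median log2 difference of all genes moved too, to 0.016 and -0.036 without Treg_resting replicate 1 and 2. It was -0.005 and -0.012 without Teff_resting replicate 1 and 2, and -0.012 with all arrays. The cause of the lower counts was not tested. Of the 21 called genes named first here, App and Klrd1 missed the threshold without each 1 of these 4 arrays and with an intensity trend. Further genes named from the lists were not checked in this way.

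The comparison of Treg with Teff in infected mice asks the same question during chronic infection. Il2ra was 29.4-fold higher in Treg (log2 difference 4.88, adjusted p = 2.23e-07) and Foxp3 20.5-fold higher (4.36, adjusted p = 1.97e-06). Penk was 18.5-fold higher, Itgae, the integrin chain CD103 that binds epithelial E-cadherin, 17.0-fold, and Gpr83 7.57-fold. Naip5, a sensor of bacterial flagellin, was 11.02-fold higher, the adhesion molecule gene Epcam 9.31-fold, the glutathione transferase gene Gsta4 8.61-fold, and Cd83 and Swap70 7.71-fold and 7.59-fold. Ctla4 was 3.97-fold higher (1.99, adjusted p = 2.08e-05), while Ikzf2 did not pass (0.51, adjusted p = 0.0969). Pdlim4 was 27.4-fold lower in Treg, Sostdc1, a secreted antagonist of BMP and Wnt signals, 11.4-fold, the MHC class I gene H2-Q2 9.99-fold, and Tdrp 6.83-fold. Lef1, Nacc2, Klrd1, Enc1, Ggt5 and the transcription factor gene Sox4 were 4.11-fold to 5.52-fold lower.

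Of the 24 Treg signature genes, 20 were higher in infected Treg than in infected Teff, 23 adjusted over the list alone. This list was the only one here to pass camera with both the preset and the estimated correlation (adjusted p = 7.33e-38 and 0.00974). Of 21 effector Treg markers 12 were higher, with 14 higher and 1 lower adjusted over the list alone, including Tnfrsf9 (2.83), Klrg1 (2.87), Itgae (4.09) and Havcr2, the inhibitory receptor TIM-3 (2.11; list adjusted p = 9.28e-13, and 0.123 with an estimated correlation). Of 28 activation and co-receptor genes 13 were higher and 1 lower, and 15 and 4 adjusted over the list alone (adjusted p = 5.42e-08, and 0.18 with an estimated correlation). Of 21 NF-kB pathway genes 5 were higher, among them Nfkb2 (0.92) and the survival gene Bcl2l1 (0.75), and 9 adjusted over the list alone (adjusted p = 2.67e-06, and 0.18 with an estimated correlation). Of 47 cell cycle genes 10 were higher, 18 adjusted over the list alone, with the replication licensing genes Mcm5 (1.06), Mcm6 (0.81) and Mcm3 (1.08) among them (adjusted p = 1.17e-10, 0.391 with an estimated correlation and 0.0923 by fry). Of 16 glycolysis genes 4 were higher, including the glucose transporter gene Slc2a3 (1.45) and hexokinase Hk2 (1.26). Adjusted over the list alone 7 were higher and 1 lower (adjusted p = 0.000594, and 0.126 with an estimated correlation).

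With the preset but not the estimated correlation, 6 lists were lower in infected Treg than in infected Teff. By fry, the T follicular helper, naive T cell, CD8 T cell and NK lists passed (adjusted p = 0.0284, 0.000939, 0.00591 and 0.0413). The Th1 and TCR signalling lists did not pass fry (adjusted p = 0.0767 and 0.209). The Th2 list (3 of 20 genes higher and 2 lower, 6 and 2 adjusted over the list alone) and the Th17 list (2 of 7 higher and 2 lower by either count) did not pass (adjusted p = 0.203 and 0.646, and 0.645 and 0.791 with an estimated correlation). Of 15 T follicular helper genes 6 were lower, including the cytokine genes Il4 (-1.59) and Il21 (-1.78), the transcription factor gene Bcl6 (-1.37) and Tnfsf8 (-1.57), while Cd200 was higher. Adjusted over the list alone 10 were lower and 1 higher (adjusted p = 1.19e-06, and 0.18 with an estimated correlation). Of 15 naive T cell genes 10 were lower, including Lef1 (-2.46) and the egress receptor gene S1pr1 (-0.87), with 10 lower and 1 higher adjusted over the list alone (adjusted p = 1.5e-09, and 0.0946 with an estimated correlation). Of 16 Th1 genes 6 were lower, among them the chemokine gene Ccl5 (-1.61) and Eomes (-1.23), but Gzmb (2.24) and Hopx (0.88) were higher. Adjusted over the list alone 7 were lower and 2 higher (adjusted p = 0.011, and 0.245 with an estimated correlation). Of 12 CD8 T cell genes 5 were lower and Cst7 was higher, with 8 lower and 1 higher adjusted over the list alone (adjusted p = 1.43e-05, and 0.123 with an estimated correlation). Of 15 NK genes 3 were lower, Prf1 (-0.87), Eomes and Klrd1, and 6 adjusted over the list alone (adjusted p = 0.000221, and 0.18 with an estimated correlation). Of 26 TCR signalling genes Rasgrp1 (-1.13) and Grap2 (-0.58) were lower and Cd2 (0.59) higher, as adjusted over the list alone (adjusted p = 0.00511, and 0.475 with an estimated correlation).

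Markers of other cells also moved with this comparison. Of 10 plasma cell genes, Prdm1 (1.74), Tnfrsf13b (0.62) and Irf4 (0.99) were higher in infected Treg, 5 adjusted over the list alone, and T cells also use Prdm1 and Irf4 (list adjusted p = 0.0019, and 0.18 with an estimated correlation). Of 11 erythroid genes, Gata1 (1.69) and the transferrin receptor gene Tfrc (0.83) were higher, 4 adjusted over the list alone (adjusted p = 0.011, and 0.245 with an estimated correlation). Gata1 was also called higher in resting Treg than in resting Teff, where the list did not pass camera (adjusted p = 0.158). Its difference is thus not particular to infected mice. Without Treg_infected replicate 3 the plasma cell, erythroid and TCR signalling lists missed the threshold (adjusted p = 0.0705, 0.0996 and 0.0857), as did the erythroid list without Teff_infected replicate 1 (adjusted p = 0.113).

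**Figure D2:**
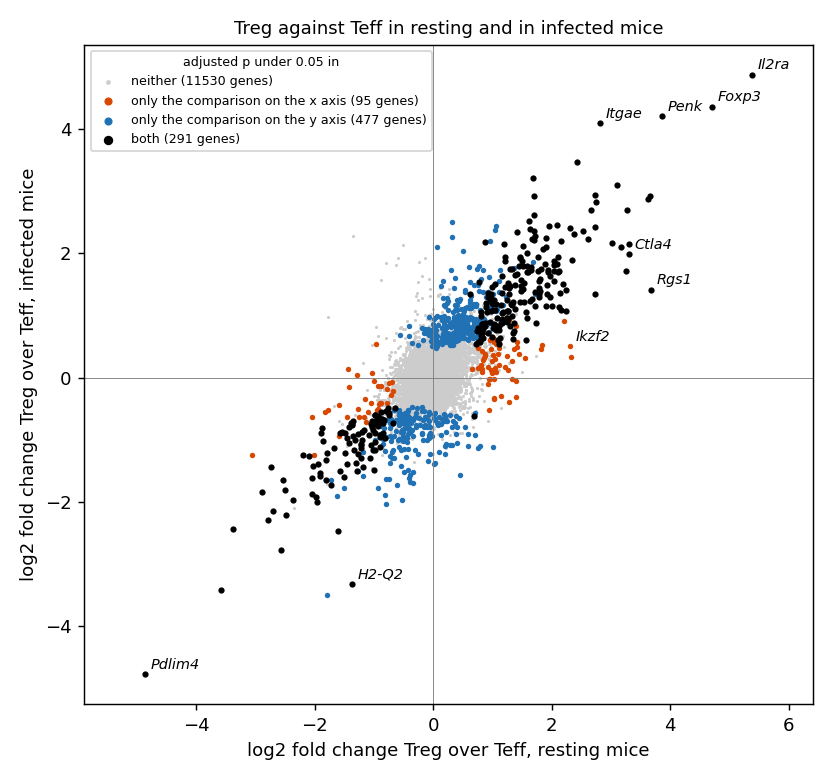
Log2 difference between Treg and Teff for each of 12393 genes, in resting mice (horizontal) and infected mice (vertical). Black points are genes called in both comparisons (291), orange those called in resting mice alone (95), blue those called in infected mice alone (477) and grey those called in neither (11530), which does not test the difference between the comparisons.

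Over all genes, 768 differed between Treg and Teff of infected mice, 476 higher and 292 lower in Treg, and 332 of them by at least 2-fold. The count was 499 without Teff_infected replicate 2, 503 without Teff_infected replicate 3 and 504 without Treg_infected replicate 2, and 614 when the 2 arrays with high neutrophil genes described below were left out, a choice made after seeing the data. The log2 ratios of 3' over 5' probe sets of spiked transcripts were 3.21, 2.74 and 1.74 in infected Treg and 2.46, 0.79 and 1.24 in infected Teff, and with this ratio as a covariate, also chosen after seeing the data, 513 genes passed, 402 of them among the 768. Of the 21 called genes named first here, Klrd1 missed the threshold without Teff_infected replicate 2 or Treg_infected replicate 2 (highest adjusted p = 0.0646), with an intensity trend and with a covariate for labelling bias.

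The differences between Treg and Teff in resting and infected mice correlated with r = 0.625 across genes, which are not independent replicates. Of the genes called in both, 192 were higher in Treg in both (9.64 expected if the calls were independent) and 98 lower in both (3.18 expected). Here too both comparisons use the same spread per gene. The only gene called in opposite directions was Bcl2, which encodes a survival protein. It was higher in resting Treg than Teff (0.70 ± 0.17, adjusted p = 0.0465) and lower in infected Treg than Teff (-0.62 ± 0.14, adjusted p = 0.0181), but the test of the difference did not pass (interaction adjusted p = 0.0775). Bcl2 was singled out after its values were seen. Of the 386 genes called in resting mice, 369 had the same sign in infected mice. Without Treg_resting replicate 1, r was 0.546.

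The comparison of infected with resting Treg asks how the regulatory cells change during the infection. Il4, the type 2 cytokine, was 10.8-fold higher in infected Treg (log2 difference 3.44 ± 0.28, adjusted p = 0.000345), Gzmb 9.27-fold (3.21 ± 0.21, adjusted p = 5.79e-05), Ifng, which encodes interferon gamma, 6.23-fold (2.64 ± 0.26, adjusted p = 0.00128) and Il10, an immune-suppressing cytokine, 6.79-fold (2.76 ± 0.38, adjusted p = 0.00528). Il21 was 5.18-fold higher, the metallothionein gene Mt1 6.52-fold and Ctla2a, related to cathepsin inhibitors, 4.78-fold. The largest increases were in Slpi, a secreted protease inhibitor (14.3-fold), and Prg2, the major basic protein of eosinophils (14.1-fold), and the red cell anion exchanger gene Slc4a1 was 6.65-fold higher. Ikzf2 fell by 1.17 ± 0.18 (2.25-fold, adjusted p = 0.00912). Il2ra (0.18), Foxp3 (0.34), Ctla4 (0.32) and Cd4 (-0.26) did not pass (adjusted p = 0.464 to 0.802).

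B cell genes were lower in infected Treg. Ms4a1, which encodes CD20, was 20.3-fold lower, Spib 7.77-fold, the B cell receptor chain gene Cd79a 6.36-fold, the kinase gene Blk 4.14-fold and the complement receptor gene Cr2 3.49-fold. Of 18 B cell genes 7 were lower, 16 adjusted over the list alone, and 0 higher (adjusted p = 1.15e-20, and 0.09 with an estimated correlation). Other genes with large decreases were the heat shock gene Hspa1b (6.31-fold), the fatty acid desaturase gene Scd1 (5.20-fold), the MHC class II chaperone gene H2-DMb2 (3.87-fold), Sfswap (3.71-fold) and the MHC class I gene H2-T24 (3.37-fold).

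Several T cell lists, which share called genes such as Gzmb and Il21, moved in infected Treg, and 0 lists of this comparison passed with an estimated correlation. Of 21 effector Treg markers 8 were higher, 13 adjusted over the list alone, including Havcr2 (1.71), Prdm1 (1.59), a transcription factor of effector Treg and plasma cells, and Fgl2 (2.01; list adjusted p = 5.99e-13, and 0.09 with an estimated correlation). Of 20 Th2 genes 5 were higher, 10 adjusted over the list alone (adjusted p = 2.2e-06, and 0.09 with an estimated correlation): Il4, Il10, Il21, Nfil3 (1.64) and Pparg. Of 16 Th1 genes 5 were higher, 7 adjusted over the list alone, among them Tbx21, the Th1 master regulator (1.11), and Ccl5 (1.22; list adjusted p = 7.05e-05, and 0.09 with an estimated correlation). Of 15 granzyme and cytotoxic granule genes, Gzmb, Gzmk (1.78) and Nkg7 (1.16) were higher, 5 adjusted over the list alone (adjusted p = 0.00177, and 0.09 with an estimated correlation). Of 15 naive T cell genes, S1pr1 (-1.11), Bach2 (-1.63) and Lef1 (-1.69) were lower, 6 adjusted over the list alone (adjusted p = 1e-05, and 0.09 with an estimated correlation).

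Lists for the cell cycle, metabolism and signalling also moved with the preset correlation. Of these only the glycolysis list passed fry (adjusted p = 0.0103). The cell cycle, oxidative phosphorylation and unfolded protein response lists did not pass fry (adjusted p = 0.103, 0.0889 and 0.116). Neither did the immediate early, NF-kB and TCR signalling lists (0.0946, 0.123 and 0.224). Of 47 cell cycle genes 0 were called, but their median log2 difference was 0.80, and 24 were higher and 1 lower adjusted over the list alone (adjusted p = 8.93e-16, and 0.301 with an estimated correlation). Cell cycle list means of the infected Treg arrays were 7.08, 7.31 and 8.21, and the mean change of the list went from 0.81 to 0.47 without Treg_infected replicate 3 (adjusted p = 4.86e-08). Of 16 glycolysis genes the aldolase gene Aldoc (0.83) was higher, 4 adjusted over the list alone (adjusted p = 0.00017, and 0.09 with an estimated correlation). Of 44 oxidative phosphorylation genes 0 were called, 6 higher adjusted over the list alone (adjusted p = 2.3e-08, and 0.311 with an estimated correlation). Of 24 unfolded protein response genes 0 were called by either count, with the list higher (adjusted p = 0.0282, and 0.352 with an estimated correlation). Of 31 immediate early and stress genes Ier3 (1.47) was higher and Hspa1b lower, 1 and 3 adjusted over the list alone, and the list was lower (adjusted p = 0.00616, and 0.09 with an estimated correlation). NF-kB pathway genes were lower as a list with 0 of 21 called, 3 lower adjusted over the list alone (adjusted p = 0.000417, and 0.301 with an estimated correlation), and of 26 TCR signalling genes Rasgrp1 (-1.39) was lower, as adjusted over the list alone (adjusted p = 0.00596, and 0.441 with an estimated correlation). Without Treg_infected replicate 3 the unfolded protein response, NF-kB and TCR signalling lists missed the threshold (adjusted p = 0.431, 0.0623 and 0.0858), as did the first without Treg_resting replicate 1 or 2 (0.067 and 0.0874), the last without Treg_resting replicate 2 (0.0517) and the immediate early list without Treg_infected replicate 2 (0.0819).

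Markers of other cells rose beside these genes. The erythroid list passed fry (adjusted p = 0.0257), but the eosinophil, plasma cell and neutrophil lists did not (0.0993, 0.0946 and 0.309). Of 11 erythroid genes Slc4a1 was higher, 7 adjusted over the list alone (adjusted p = 2.7e-05, and 0.09 with an estimated correlation). Of 18 eosinophil, basophil and mast cell genes Prg2 was higher, 3 adjusted over the list alone (adjusted p = 0.00667, and 0.311 with an estimated correlation). Of 10 plasma cell genes Prdm1 was higher, 2 adjusted over the list alone (adjusted p = 0.0185, and 0.301 with an estimated correlation). Of 13 neutrophil genes 0 were called, 2 higher adjusted over the list alone (adjusted p = 0.0156, and 0.522 with an estimated correlation). The eosinophil, plasma cell and neutrophil lists missed the threshold without Treg_infected replicate 3 (adjusted p = 0.0791, 0.198 and 0.179) and without Treg_resting replicate 1 (0.157, 0.0584 and 0.157), and the plasma cell list without Treg_resting replicate 2 (0.0517). A pair of arrays stood apart: the neutrophil list mean was 7.19 in Treg_infected replicate 3 and 6.38 in Teff_infected replicate 2, against 4.33 to 5.26 in the other arrays, and Camp reached 9.82 and 9.01. RNA labelling differed too, with log2 ratios of 3' over 5' probe sets of spiked transcripts of 3.21, 2.74 and 1.74 in infected Treg, against 1.35 and 1.44 in resting Treg.

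**Figure D3:**
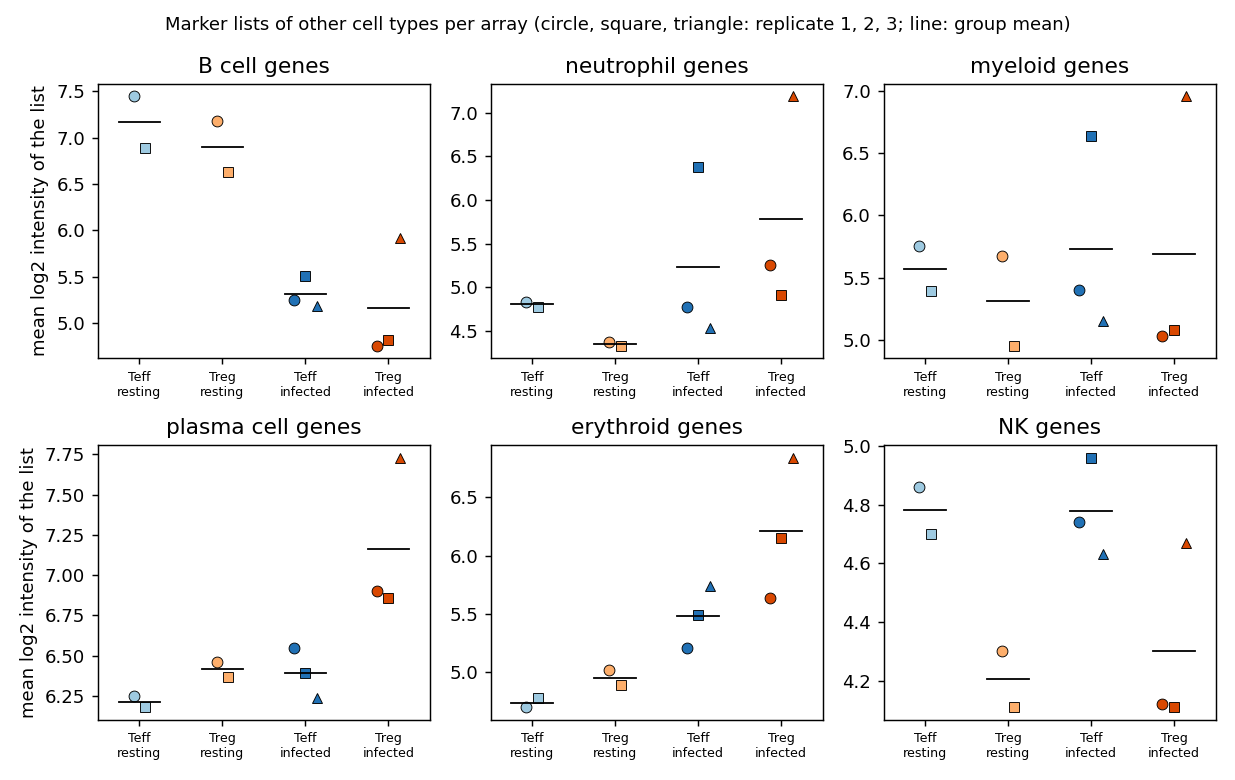
Mean log2 intensity of the genes of 6 marker lists of other cells on each of the 10 arrays, by group, with points for arrays and lines for group means. The B cell mean lay between 6.63 and 7.45 in resting and between 4.75 and 5.92 in infected samples, and the neutrophil mean was highest in Treg_infected replicate 3 (7.19) and Teff_infected replicate 2 (6.38).

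Over all genes, 127 differed between infected and resting Treg, 78 higher and 49 lower in infected Treg, and 99 by at least 2-fold. The count was 56 and 21 without Treg_resting replicate 1 and 2, 59 and 278 without Treg_infected replicate 2 and 3, 264 without the 2 arrays with high neutrophil genes, 66 with the labelling ratio as a covariate, 48 with these groups alone, and 201 and 283 with the mean of probe sets or single probe sets. On leaving out an array, 12 of the 21 called genes named first here missed the threshold, each without Treg_resting replicate 1 or 2 and 6 of them also without Treg_infected replicate 1 or 2: Slpi, Prg2, Il10, Slc4a1, Il21, Ctla2a, Cd79a, Hspa1b, H2-DMb2, Sfswap, H2-T24 and Ikzf2 (highest adjusted p = 0.0553 to 0.292), while Il4, Gzmb, Mt1, Ifng, Ms4a1, Spib, Scd1, Blk and Cr2 passed without any 1 array.

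The comparison of infected with resting Teff asks how the CD25- cells change. Il4 was 14.3-fold higher in infected Teff (3.83 ± 0.28, adjusted p = 8.64e-05), Ifng 10.2-fold (3.34 ± 0.26, adjusted p = 0.000101), Gzmb 7.32-fold (2.87 ± 0.21, adjusted p = 8.64e-05) and Il21 6.24-fold. Rgs1 was 5.85-fold higher, Klrg1 5.44-fold, the oxygen-sensing hydroxylase gene Egln3 5.19-fold, Fgl2 4.70-fold, Clec2d 4.42-fold and Ctla4 3.08-fold, and H2-Q2 was 8.14-fold higher. B cell genes were again lower: Ms4a1 24.5-fold, Cd79b 10.04-fold, Cd79a 5.81-fold, Spib 4.196-fold, Cr2 4.16-fold, and Cd74, the MHC class II invariant chain, 3.93-fold. Scd1 was 10.9-fold lower, H2-DMb2 4.36-fold, the chemokine receptor gene Cxcr4 4.32-fold and Mef2c 3.93-fold. Foxp3 (0.69), Il2ra (0.68), Ikzf2 (0.64) and Cd4 (-0.47) did not pass (adjusted p = 0.113 to 0.571).

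In infected Teff 14 lists passed with the preset correlation and 0 with an estimated one. The cell cycle, oxidative phosphorylation and erythroid lists did not pass fry (adjusted p = 0.246, 0.246 and 0.075), while the rest of the 14 did. Of 15 T follicular helper genes 8 were higher, 11 adjusted over the list alone, including the co-stimulator Icos (1.31) and Pdcd1, which encodes PD-1 (1.63; list adjusted p = 8.11e-16, and 0.0701 with an estimated correlation). Of 16 Th1 genes 7 were higher, 9 adjusted over the list alone, among them Eomes (1.48) and Ccl5 (1.32; adjusted p = 1.47e-11, and 0.0701 with an estimated correlation). Of 20 Th2 genes Il4 and Il21 were higher, 7 adjusted over the list alone (adjusted p = 1.43e-07, and 0.0801 with an estimated correlation). Of 7 Th17 genes Il21 alone was higher, with 3 higher and 1 lower adjusted over the list alone (adjusted p = 0.0257, and 0.12 with an estimated correlation). Il21 is counted in the T follicular helper, Th2 and Th17 lists alike. Of 21 effector Treg markers 6 were higher, 13 adjusted over the list alone (adjusted p = 8.11e-16), and of 24 Treg signature genes 5 were higher and Swap70 lower, 15 and 1 adjusted over the list alone (adjusted p = 2.81e-10), each 0.0701 with an estimated correlation. Those 5 were Gzmb, Klrg1, Ctla4, Tnfrsf4 and Socs2 (1.98). Of 28 activation and co-receptor genes 5 were higher, including Tnfsf11 (1.73) and Tnfrsf4 (1.61), with 14 higher and 1 lower adjusted over the list alone (adjusted p = 1.86e-08, and 0.0981 with an estimated correlation).

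Granule and CD8 T cell lists were higher in infected Teff with the preset correlation, but the NK list was not: of its 15 genes 3 were higher and 2 lower (Prf1 and Klrc1), and 3 and 3 adjusted over the list alone (adjusted p = 0.885, and 0.949 with an estimated correlation). Of 15 granzyme and granule genes 4 were higher, Gzmb, Gzma (1.76), Gzmk (1.40) and Nkg7 (1.17), and Prf1 was lower, with 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.0017, and 0.0701 with an estimated correlation). Of 12 CD8 T cell genes 5 were higher, including Cst7 (1.65), with 7 higher and 2 lower adjusted over the list alone (adjusted p = 0.000145, and 0.0981 with an estimated correlation). Of 15 naive T cell genes S1pr1 (-0.63) was lower, 6 adjusted over the list alone (adjusted p = 8.78e-05, and 0.0981 with an estimated correlation). Of 47 cell cycle genes 0 were called, 3 higher adjusted over the list alone (adjusted p = 1.47e-11, and 0.362 with an estimated correlation), and of 44 oxidative phosphorylation genes Ndufa4 (0.78) was, as adjusted over the list alone (adjusted p = 5.4e-05, and 0.506 with an estimated correlation; 0.13 at the preset correlation without Teff_resting replicate 1). Of 18 B cell genes 9 were lower, 16 adjusted over the list alone (adjusted p = 2.19e-20, and 0.0701 with an estimated correlation). Of 11 erythroid genes 0 were called by either count, with the list higher (adjusted p = 0.000173, and 0.0981 with an estimated correlation).

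Over all genes, 207 differed between infected and resting Teff, 131 higher and 76 lower in infected Teff, and 133 by at least 2-fold. The count was 29 and 58 without Teff_resting replicate 1 and 2, 77 and 137 without Teff_infected replicate 1 and 2, 329 without Treg_infected replicate 3, 228 without the 2 arrays with high neutrophil genes, 354 with the labelling covariate and 529 with array weights. On leaving out an array 9 of the 21 called genes named first here missed the threshold (highest adjusted p = 0.0947 to 0.232): Il21, Egln3, Cd79a, H2-DMb2, Cxcr4, Spib, Mef2c and Cd74 without Teff_resting replicate 1, Cd79a and Cxcr4 also without Teff_resting replicate 2, Cd79a, Spib and Mef2c also without Teff_infected replicate 1, and Clec2d without Teff_resting replicate 2 or each infected Teff array.

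**Figure D4:**
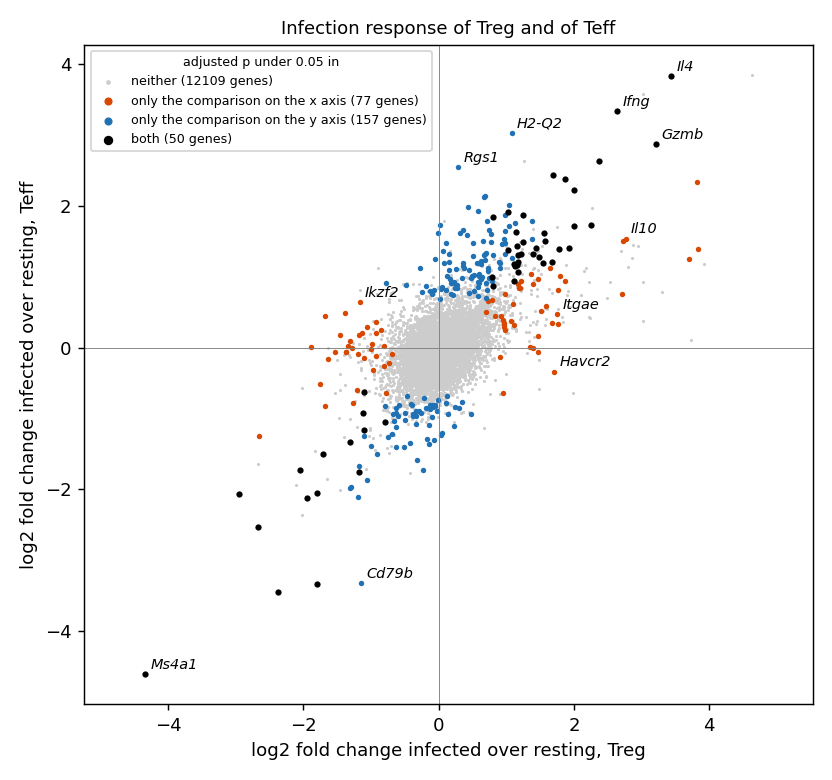
Log2 difference between infected and resting mice for each of 12393 genes, in Treg (horizontal) and Teff (vertical). Black points are genes called in both cell types (50), orange those called in Treg alone (77), blue those called in Teff alone (157) and grey those called in neither (12109), which does not test the difference between the cell types.

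The infection responses of Treg and Teff correlated with r = 0.552 across genes. Called genes that were higher in both cell types numbered 35 (0.82 expected if the calls were independent), 15 were lower in both (0.3 expected) and 0 moved in opposite directions. The calls are not independent, because both comparisons use the same spread per gene. Il4, Ifng, Gzmb and Il21 were among those higher in both, and Ms4a1, Cd79a, Cr2, Spib and Scd1 among those lower in both. Of the 127 genes called in Treg, 106 had the same sign in Teff, and of the 207 called in Teff, 187 had the same sign in Treg.

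The interaction asks which genes responded differently in the 2 cell types, and 2 of 12393 genes passed. Havcr2 responded more in Treg (interaction 2.05 ± 0.27, adjusted p = 0.045), with a mean of 3.41 in resting and 5.12 in infected Treg, against 3.35 and 3.02 in Teff, so 3 of the 4 means lay under the 25th percentile of all genes (3.53). Rgs1 responded less in Treg (-2.27 ± 0.30, adjusted p = 0.045), where it was 9.66 and 9.94, against 5.98 and 8.53 in Teff. The next genes did not pass: Nedd4l (1.503, adjusted p = 0.07), Padi2 (1.59, 0.0775), Cd79b (2.18, 0.125) and Tanc1 (1.40, 0.171) in one direction, and Ikzf2 (-1.81, adjusted p = 0.0527), Klrb1b (-1.36), Socs2 (-1.54) and Klrb1f (-1.69, adjusted p = 0.07 for each of the last 3) in the other. Foxp3 (-0.34), Il2ra (-0.50), Ctla4 (-1.31) and Cd4 (0.21) did not pass (adjusted p = 0.14 to 0.991).

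As lists, T follicular helper genes responded less in Treg than in Teff (mean -0.87, adjusted p = 4.87e-11, and 0.395 with an estimated correlation), with 0 of 15 called and 4 lower adjusted over the list alone, the smallest p-values being those of Tnfsf8 (-2.02), Pdcd1 (-1.63), Bcl6 (-1.41) and Cxcr5 (-1.37). The Treg signature (mean -0.41, adjusted p = 1.31e-05, and 0.514 with an estimated correlation) had 0 of 24 called, 2 higher and 8 lower adjusted over the list alone. The activation and co-receptor list (mean -0.36, adjusted p = 1.31e-05, and 0.514 with an estimated correlation) had Havcr2 called higher, and 1 higher and 6 lower adjusted over the list alone. By fry these 3 lists did not pass (adjusted p = 0.462, 0.462 and 0.667). At an unadjusted p under 0.05, 750 genes differed, where 620 would by chance. The count of 2 became 0 with a block for the replicate number or the labelling covariate, 1 with quantile normalization or genes above the median level, 4 with array weights, 5 with an intensity trend, 6 with single probe sets, 8 without Treg_infected replicate 3 and 0 or 1 without each other array, and 3 without the 2 arrays with high neutrophil genes.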

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

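The tests of cells in a single sample, of labelling bias, of residual B cells and of the 2 arrays with high neutrophil genes were chosen after the results were seen, while the splits of the arrays, the gate and the lists of other cell types were set before.

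The difference between the infection responses of Treg and Teff passed the interaction test for Havcr2 (2.05) and Rgs1 (-2.27), and for the lists of T follicular helper (mean -0.87), Treg signature (mean -0.41) and T cell activation genes (mean -0.36). With an estimated correlation these 3 lists did not pass (adjusted p = 0.395, 0.514 and 0.514), and Havcr2 and Rgs1 each missed the threshold on leaving out 1 array for 8 of the 10 arrays. Of the 1555 probe sets without a listed gene, which the comparisons left out, 29 passed the threshold between Treg and Teff in resting mice, 58 between Treg and Teff in infected mice, 20 between infected and resting Treg and 12 between infected and resting Teff.

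Treg and Teff of infected mice are the only groups with 3 arrays each. In a fit of these 6 arrays alone 561 genes passed in the real split and at most 1 in the other splits, so 1 of the 10 splits, the real one, gave as many. With 10 splits the share cannot fall under 0.05.

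The 78 genes higher in infected than in resting Treg had a median log2 change of 1.38. Without Treg_infected replicate 3, 76 of them passed, with a median of 1.46. Their rise thus does not rest on neutrophils, other myeloid cells or plasma cells in that array alone. The threshold favours genes with a small spread within groups, so genes raised in that array alone were unlikely to be among the 78. Of 13 neutrophil genes 0 were called, although their median change was 1.88. With the labelling covariate 78 stayed higher at 81.6% of the median (1.13). Of these, 22 passed, because the change shrank and the median standard error grew from 0.226 to 0.258. Of all 127 called genes, 37 passed with the covariate. The slope on the ratio is estimated from the spread within groups, which the threshold kept small in the 78 genes. A small slope was therefore likely beforehand, so this is weak evidence against more 3' biased labelling as the whole cause. Other cells in more of the samples remain a candidate source for some of these genes: 4 of the 10 lists of other cells rose with the preset correlation (estimated-correlation adjusted p = 0.09 to 0.522), and without Treg_infected replicate 3 the erythroid list passed (mean 0.94, adjusted p = 5.15e-05) while the neutrophil, plasma cell and eosinophil lists stayed higher (means 0.73, 0.46 and 0.45) but missed the threshold. Of the 78 genes 8 are in a list of other cells, 3 of them in a rising list (Prg2 at 7.38, Slc4a1 at 7.11 and Prdm1 at 8.22 in infected Treg), while the immunoglobulin gene Ighg3, outside the lists, rose by 3.70 and Jchain was 9.80, 8.76 and 11.69 in infected against 7.46 and 6.11 in resting Treg (both chosen after their values were seen), although the CD4 sort and erythrocyte depletion should remove such cells. Activated CD25+ conventional T cells in the gate cannot be told apart from a response of Treg, because Foxp3 changed by 0.343 (95% interval -0.278 to 0.965): the bound of 1 standard error (0.284) set beforehand was too weak, as the covariate turned the value to -0.215, and the 22 signature genes moved both ways (median 0.249, 10 lower, 4 past the threshold higher and 1 lower, Ikzf2 at -1.17, while Gpr83, also named beforehand, went from 9.60 to 9.01, adjusted p = 0.131).

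All 18 measured B cell genes were lower in infected mice in both cell types, with median log2 changes of -1.68 in Treg and -1.79 in Teff. The labelling covariate left 86.3% of the change averaged over both cell types (-1.11 and -1.89). In Treg, whose infected arrays had higher ratios, the median moved from -1.68 to -1.11. Treg_infected replicate 3 had the lowest ratio of its group (1.74 against 3.21 and 2.74) and the highest B cell list mean (5.92 against 4.75 and 4.81). Labelling or other cells in that array may therefore account for this shift, and these cannot be told apart. In Teff the ratios of infected arrays (2.46, 0.79 and 1.24) lay on both sides of those of resting arrays (1.78 and 1.5). More 3' biased labelling is therefore argued against as the whole cause of the fall, at least in Teff. Fewer residual B cells in the infected samples may account for it: the changes of the 18 genes, 0 of which are in another list, correlated between Treg and Teff with r = 0.767 across genes (0.552 for all genes), and the 7 that passed in Treg, Ms4a1 among them, also passed in Teff, though any cause shared by Treg and Teff would give this. Cd79b fits less well, with -1.14 in Treg and -3.33 in Teff, the abundant Cd74 did not pass in Treg (-1.30, adjusted p = 0.0797, against -1.97 in Teff), and the MHC class II depletion and the CD4 sort should remove B cells from every sample. Whether the depletion worked better or the nodes held another mix of cells in infected mice was not tested and stays open.

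Neutrophil and myeloid genes were high in Treg_infected replicate 3 and Teff_infected replicate 2, by medians of 1.85 and 0.95 over their groups across 38 genes. Both arrays have the lowest spike-in ratio of their group (1.74 and 0.79). The within-group slopes of the other 8 arrays predict medians of -0.165 and -0.143, with median upper 95% bounds of 0.478 and 0.412. These slopes rest largely on a single pair of arrays, Teff_infected replicates 1 and 3 (ratios 2.46 and 1.24), because the other pairs lie closer together. They are thus only weak evidence against the labelling bias. The same other cells in both sorted samples are a candidate source, since the deviations of the 38 genes correlated with r = 0.83 (0.399 for all genes) and the abundant transcripts rose in both, as Chil3 to 11.41 and 11.71 and S100a8 to 11.07 and 10.69, though any shared cause of the rise would give such a correlation. Of the 13 neutrophil genes 0 and of the 25 myeloid genes 1 is also in another list, and 4 and 9 lay above the median of all genes over the arrays. The CD4 sort should remove such cells, and whether the 2 samples came from the same mouse is not stated.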

How the results depend on the processing

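The covariate for labelling bias, leaving out the 2 arrays with high neutrophil genes and the crossed block were chosen after seeing the data, and the other alternatives before; where no reason is given, the cause was not tested. Counts not given here stayed within 1.5 times those reported. Leaving out 1 array at a time changes the number of arrays. The counts then ran from 183 to 459 for Treg against Teff in resting mice, from 499 to 915 in infected mice, from 21 to 278 for infection in Treg, from 29 to 329 for infection in Teff, from 0 to 8 for the interaction, and from 56 to 70 for lists. The correlation of the infection responses ran from 0.487 to 0.569 and that of Treg against Teff from 0.546 to 0.619, the lowest without Treg_resting replicate 1. Stricter thresholds lowered counts by construction: at least 2-fold gave 332 for Treg against Teff in infected mice and 133 for infection in Teff, and an adjusted p of 0.01 gave 196, 385, 44, 52 and 0 in the order of the comparisons. The infection count of Treg was 201 with the mean of all probe sets, 283 as single probe sets (which also counts more units), 48 with these groups alone, 66 with the labelling covariate and 264 without the 2 arrays. That of Teff was 529 with array weights and 354 with the covariate. The 2 arrays with high neutrophil genes had the lowest labelling ratio of their groups (1.74 and 0.79). Changes with the covariate can therefore come from labelling or from other content of these arrays. With the compared groups alone, the count rose to 423 for Treg against Teff in resting mice and 263 for infection in Teff. It fell to 561 for Treg against Teff in infected mice. The interaction count of 2 became 1 with quantile normalization and with genes above the median level, 5 with an intensity trend, 4 with array weights, 6 as single probe sets and 0 with the covariate. Without the 2 arrays the reported and new counts shared 369, 527, 115, 158 and 1 genes. Among genes above the median level the correlation of Treg against Teff rose to 0.685.

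With the replicate number as a block the counts were 329 and 707 for Treg against Teff in resting and infected mice, 128 and 204 for infection in Treg and Teff, 0 for the interaction and 65 for lists. In resting mice the deviations of 2 arrays per group are fixed by centring, so r across genes is a single value (-0.12 by number, 0.12 crossed). In infected mice arrays of the same number gave 0.29, -0.25 and -0.24, against 0.4 for Teff replicate 2 with Treg replicate 3 and for Teff replicate 3 with Treg replicate 2, so the numbers do not show which arrays share a mouse. The crossed block was run in resting mice only and gave 352.

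With an estimated correlation 5 of the 58 list calls passed, and fry kept 37 of them. Lists were not run with the covariate, array weights, an intensity trend or the compared groups alone. Over the alternatives run for them, list results kept their direction and side of the threshold 867 times and lost the call 108 times, and 0 reversed. Over the alternatives run for them, named genes kept both 1905 times, lost the call 98 times, gained it 12 times and reversed 7 times. Each reversal was of a gene that did not pass. Single probe sets, the stricter thresholds and the crossed block were not among these alternatives. Cd4 reversed in Treg against Teff of resting mice, infection in Treg and the interaction: to 0.239 and -0.414 in the first and last without Treg_resting replicate 1, to 0.357 in the middle one without Treg_resting replicate 2, and in the interaction to -0.359 with the mean of probe sets and -0.201 with the covariate. Leaving out single arrays, the Cd4 values of these comparisons ran from -0.998 to 0.239, from -0.88 to 0.357 and from -0.414 to 0.823. In the infection comparison of Treg, Il2ra reversed to -0.153 with the mean of probe sets and Foxp3 to -0.215 with the covariate. The values carry no detection calls, so changes of genes near background, under about 3.53 on the log2 scale, are limited by signal.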

Other observations

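The test of dividing cells was set before the results were seen, and the values of the other genes below were chosen after.

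Infected Treg also differed from resting Treg in genes outside the named set. Among the 78 genes higher in infected Treg were Ltb4r1, a leukotriene B4 receptor (log2 change 1.87), the chemokine gene Ccl1 (1.58), Ccr2, a chemokine receptor of monocytes and activated T cells that is also in the myeloid list (1.56), Id2, an inhibitor of E proteins (1.25), the galectin gene Lgals1 (1.18), Casp1, which encodes an inflammatory caspase (1.03), and Cxcr3, a receptor linked to Th1 cells (0.70). Bcl2, a survival gene, fell by 1.38 ± 0.15 in infected against resting Treg (adjusted p = 0.00152), with a change of -0.06 in Teff (adjusted p = 0.911) and an interaction that did not pass (adjusted p = 0.0775).

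More dividing cells in infected Treg are a candidate explanation for part of the genes higher there. The rule set beforehand, a rise of the cell cycle list by camera and a median change above that of all genes, was met. The list adjusted p was 8.93e-16 with the preset correlation, and the median change was 0.801 against 0.021 for all genes. The estimated correlation, required in addition, was not in that rule, and with it the list adjusted p was 0.301. With fry, also outside that rule, the list adjusted p was 0.103. Of the 47 genes 45 were higher, but 0 passed the threshold. Without Treg_infected replicate 3 the mean change of the list was 0.47, against 0.81 with it. The highest list mean, 8.21, was in Treg_infected replicate 3, the array that also had high neutrophil and plasma cell genes, so dividing T cells and dividing cells of other types cannot be told apart here.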
